A study of Mus musculus with 10 samples.

How the data were processed

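Gene expression was measured in the amygdala of 3-month-old mice of 2 genotypes, wild type (C57BL/6) and neuropsin-/-. Neuropsin is the serine protease encoded by Klk8, and the knockout line had been backcrossed to C57BL/6 for 12 generations, per the labels' protocols. There were 5 arrays per genotype. The design text gives 15 animals per genotype and 3 animals to an array, which was read as 5 separate pools of RNA per genotype. Brains were perfused with cold saline and sliced on a vibrating microtome, the amygdala was cut from a coronal slice, and ribosomal RNA was depleted before labelling, per the labels' protocols. The arrays were GeneChip Mouse Exon arrays, on which a probe set covers about 1 exon, so a gene is measured by many probe sets.

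The deposited values are log2 expression values, 1 per probe set and array, which the authors made by RMA (background correction, quantile normalization and summary of the probes of a probe set) in Affymetrix Expression Console, per the labels and the submitters' processing notes. Software versions and the genome build of the array's annotation are not given in the sources used here. The table held 1256831 probe sets, of which 20744 were at 0 on every array and bore no gene name. Scanner images were not used here, so another background correction and a slide or scan day as a block were not run. The median value of all probe sets lay between 4.95 and 5.03 on the 10 arrays. Precision is limited by the number of arrays, 5 per genotype.

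Probe sets were named through the platform annotation. Of the 1256831 probe sets, 325444 had a gene symbol, 318760 of these with 1 gene and 6684 with several, and 931387 were unnamed here. The 318760 probe sets carried 22296 symbols, of which 18006 were current in the reference gene table (assembly GRCm38.p6), 4227 were updated through a synonym held by exactly 1 gene and 63 were kept as given. No gene was named from a probe set with several genes, except where probe sets of near-identical genes are described as such. Chromosomes and gene order are those of the reference table. No coordinates are given, because the build of the array annotation is not given.

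Probe sets were tested when their mean over the 10 arrays exceeded the median of all probe sets, 4.94 on the log2 scale, which left 628415. The gene level was the mean log2 value of a gene's probe sets that passed this filter and had exactly 1 gene, for genes with at least 3 of them: 16367 genes with 238335 probe sets, a median of 11 per gene. Knockout and wild type were compared with limma version 3.58.1 (lmFit and eBayes, no trend, not robust) in R version 4.3.3, with data.table version 1.17.8, on the log2 values of all 10 arrays, without covariates. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method, and the threshold was an adjusted p of 0.05. Differences are knockout minus wild type, and standard errors (SE) are those of the fit. Relative use of exons within a gene was tested with limma's diffSplice, with the Simes p of each gene, over the probe sets of the 16367 genes. Klk8 was also tested by exact two-sided permutation of the 10 arrays over its 9 probe sets, without the intensity filter.

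Gene lists (37) were fixed before the data were examined, from textbook knowledge of the amygdala, of neuropsin and its partners, and of the cell types and neighbouring brain regions that a dissection can hold. Of their 784 genes, 682 were measured (87.0%). The 35 lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists, and again with the correlation estimated from the data and with fry. Counts adjusted over the list alone use the Benjamini-Hochberg adjustment within that list. Blood cell and sex-linked genes had too few measured members for a test.

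The genes named in the text follow a rule fixed before the data were examined: Klk8; every gene that passed, and, since fewer than 20 passed, the genes of smallest p up to 10 higher and 10 lower, given as values; 2 to 4 members of each list with the smallest p; 9 background genes of neuropsin (Ephb2, Fkbp5, Grin1, Grin2a, Grin2b, Nrg1, Erbb4, L1cam and Fn1); and up to 10 genes of smallest p in the probe set and exon usage tests. Predicted genes could be given by number only. Other genes are said to have been chosen after their values were seen.

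Alternatives planned before the data were examined were quantile normalization of the table again, centring each array on its median, no intensity filter and a stricter one (the 75th percentile of all probe sets, 6.50), the replicate number as a block, each array left out in turn, array weights, a trended and robust variance prior, the median or median polish over a gene's probe sets, at least 1 probe set per gene, a minimum log2 change of 0.5, a threshold of 0.1, an F test per gene for exon usage, and the estimated correlation and fry for lists. Alternatives chosen after seeing the data were leaving out the 2 arrays farthest out on the first principal component, that component as a covariate, the mean of the hypothalamus list as a covariate, and an exon usage test with a separate variance for each probe set. The real comparison was also set against 100 of the 126 ways to split the 10 arrays into 5 and 5, and against 60 of them for exon usage.

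Each limma test was checked on simulated data with known changes and the spread of the real arrays. Genes and probe sets were drawn independently, so correlation between genes and structure shared by arrays were not part of this check. At the gene level, 68 of 100 genes changed by 0.5 on the log2 scale and 97 of 100 changed by 1 were recovered, with 10 false calls among 16367 genes. At the probe set level, 22 of 100 changed by 1 and 76 of 100 changed by 2 were recovered, with 2 false calls among 628415. The exon usage test recovered 62 of 100 changes of 1 but made 794 false calls among 16367 genes when each probe set had its own spread, and 16 when the probe sets of a gene shared their spread. With a separate variance for each probe set it recovered 24 of 100 changes of 1 and 87 of 100 changes of 2, with 6 false calls among 16367 genes. For lists, 4 of 5 shifted by 0.1 and 5 of 5 shifted by 0.2 were recovered among 35. Members of a list were uncorrelated there, while the correlation estimated from the real arrays reached 0.787, for myelin genes.

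Figures were drawn with matplotlib version 3.10.9.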

Results

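The data were 10 exon arrays of mouse amygdala, 5 from wild-type mice and 5 from mice without a working neuropsin gene (Klk8), each array holding RNA of 3 animals. The design asks how the loss of neuropsin, a secreted serine protease, changes gene expression in this brain region. Gene levels correlated between any 2 arrays at 0.958 to 0.987, over genes, which are not independent replicates, and no 2 arrays shared more than 0.0123% of their tested values exactly. The first principal component of the gene levels carried 35.5% of the variance and did not separate the genotypes. Wild-type arrays 4 and 5 stood apart on it, at 20.5 and 23.5, while the other 8 arrays lay between -14.2 and 7.45. Among the knockout arrays, arrays 4 and 5 were also the highest on it, at 7.45 and 3.14. The second component carried 13.9% and separated the genotypes, at 1.46 to 15.9 in wild type and -10.2 to -1.02 in the knockout. The labels give no batch. The p-values measure the spread between arrays, each read as a pool of animals, including any structure that arrays with the same replicate number share.

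No probe set of the targeted gene passed after adjustment over its 9 probe sets, which 1 probe set alone could not have done. The mean of all 9 Klk8 probe sets was 5.17 ± 0.27 (SD, n = 5) in wild type and 5.02 ± 0.29 (SD, n = 5) in the knockout, a difference of -0.15 with an SE of 0.18 (exact permutation p = 0.413, two-sided). For this Klk8 level in knockout and wild type the median over the 9 probe sets gave a larger difference, -0.61 (exact permutation p = 0.0794), and the mean gave -0.06 without wild-type array 1, -0.25 without wild-type array 3 and -0.04 without knockout array 2. Probe set 4485756 was at 5.70 ± 0.23 in wild type and 4.67 ± 0.70 in the knockout, a difference of -1.03 with an SE of 0.33. Its exact permutation p of 0.00794 is the smallest that 5 arrays against 5 allow, with all knockout arrays below all wild-type arrays. After adjustment over the 9 probe sets it was 0.0714, the lowest value that 1 probe set alone can reach. Probe set 4837809 differed by -0.62 (SE 0.25, exact permutation p = 0.0476) and probe set 5496921, below the intensity filter, by -0.43 (SE 0.15, exact permutation p = 0.0317), each at 0.143 after the adjustment. The other 6 probe sets differed by -0.49 to 0.64, with exact permutation p-values of 0.230 or more. Over the 5 probe sets above the intensity filter the difference was -0.39 (exact permutation p = 0.0476), and the gene did not pass among all genes (limma adjusted p = 0.693). The labels do not say which exons were removed, and a probe set outside the deleted part checks nothing.

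**Figure D1:**
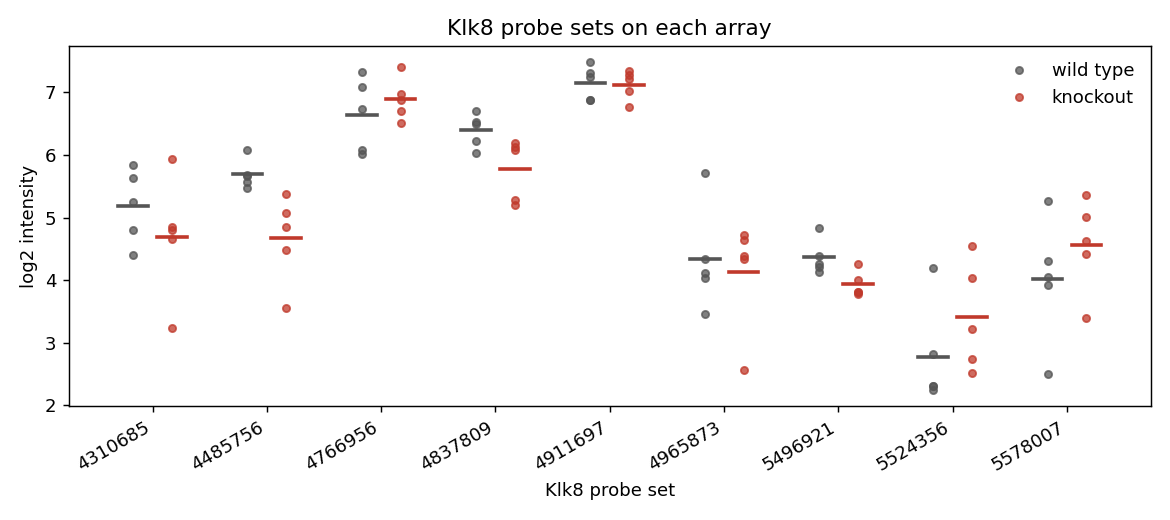
Log2 intensity of the 9 Klk8 probe sets (horizontal axis) on each of the 5 wild-type (grey) and 5 knockout (red) arrays; dots are arrays and horizontal bars are group means. Probe set 4485756 had a mean of 5.70 in wild type and 4.67 in the knockout, while probe set 4911697 was at 7.16 and 7.12.

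At the gene level 4 genes changed, 3 lower and 1 higher in the knockout. Myo7a, an unconventional myosin known from hair cells, fell from 6.89 ± 0.10 to 6.16 ± 0.07 (SD, n = 5 each), a log2 change of -0.73 with an SE of 0.07. Hbb-b1, a beta-globin gene, fell from 9.39 ± 0.44 to 7.58 ± 0.37, a change of -1.81 with an SE of 0.20, or 3.51-fold. Tmem159, a protein of lipid droplets, fell from 6.78 ± 0.17 to 6.11 ± 0.09, a change of -0.66 with an SE of 0.09. Pisd-ps3, a pseudogene of the mitochondrial phosphatidylserine decarboxylase Pisd, rose from 8.20 ± 0.28 to 9.11 ± 0.14, by 0.91 with an SE of 0.12. For all 4 genes the 5 knockout arrays lay entirely to one side of the 5 wild-type arrays. The limma adjusted p-values were 0.0017 for Myo7a, 0.00315 for Hbb-b1 and 0.0127 for both Tmem159 and Pisd-ps3, over 16367 genes.

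Myo7a, Tmem159 and Hbb-b1 are genes of chromosome 7, which also carries Klk8, although the reference table gives Hbb-b1 no place in the gene order. Hbb-b1 rested on 3 probe sets, which differed by -1.04 to -2.21, while the 6 probe sets shared by Hbb-b1 and Hbb-b2 differed by -0.14 to -0.49 and the 10 shared by the alpha-globin genes by -0.28 to -0.43 (globin probe sets were chosen after their values were seen). None of these shared probe sets passed (smallest unadjusted p = 0.0281). Pisd-ps3 shares sequence with near-identical copies, and the change cannot be assigned to that copy. Without knockout array 2, 3 or 5 only 2 genes passed, since Pisd-ps3 and Tmem159 then had adjusted p-values of 0.0543 to 0.0686. Tmem159 also missed the threshold without wild-type array 3 (0.0583) or knockout array 1 (0.0547) and with the median over its probe sets (0.629). It missed it with the replicate number as a block too.

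**Figure D2:**
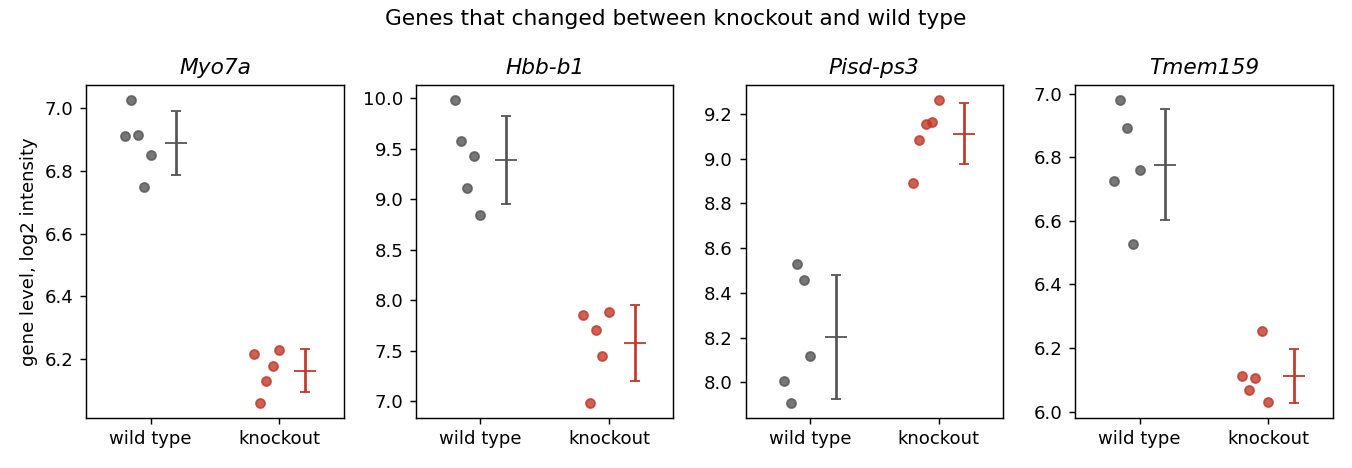
Gene level, in log2 intensity, of the 4 genes that changed, on each wild-type (grey) and knockout (red) array; dots are arrays, and the bar with whiskers beside them is the mean ± SD of 5 arrays. Myo7a, Hbb-b1 and Tmem159 fell, and Pisd-ps3 rose, from 8.20 to 9.11.

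Beyond these, 1142 genes had an unadjusted limma p under 0.05, against 818 expected by chance, 465 of them higher and 677 lower in the knockout. In 253 genes (1.55%) the groups did not overlap, where chance gives 0.794%. None of the following genes passed, and their adjusted p-values were 0.213 to 0.357. On the lower side Snrpa1, a spliceosome protein, differed by -0.46 (SE 0.09), Emc10, a subunit of the endoplasmic reticulum membrane complex, by -0.47 (SE 0.09), Gng8 by -0.39 (SE 0.08) and Trim61 by -0.48 (SE 0.09). With the median over its probe sets the gene Snrpa1 differed by only -0.012. Snrpa1, Emc10 and Gng8 are also chromosome 7 genes. On the higher side Pisd-ps2, another Pisd pseudogene, differed by 0.43 (SE 0.08), Tma16 by 0.41 (SE 0.08), Esf1 by 0.48 (SE 0.10), Cfap44 by 0.53 (SE 0.12), Spink8 by 0.48 (SE 0.11) and Galnt18, on chromosome 7, by 0.29 (SE 0.07). Speer4b was at -0.46 (SE 0.10), and 5 predicted genes completed the set, 3 higher and 2 lower.

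Genes known as partners or targets of neuropsin did not pass. Fkbp5, a co-chaperone of the glucocorticoid receptor, was at 7.40 ± 0.18 (SD, n = 5) in wild type and 7.84 ± 0.31 in the knockout, a difference of 0.43 with an SE of 0.14 and a limma adjusted p of 0.630. The NMDA receptor subunit genes Grin2b and Grin2a differed by 0.24 (SE 0.07, adjusted p = 0.582) and 0.21 (SE 0.07, adjusted p = 0.693), with all 5 knockout arrays above all 5 wild-type arrays in both. Grin1 differed by 0.07 (SE 0.07). L1cam, a cell adhesion molecule cleaved by neuropsin, differed by 0.17 (SE 0.07, adjusted p = 0.698) and Fn1, fibronectin, by 0.17 (SE 0.09). The receptor Ephb2 differed by 0.06 (SE 0.08), and the growth factor Nrg1 and its receptor Erbb4 by 0.02 (SE 0.08) and 0.03 (SE 0.08). As a list, 9 neuropsin substrates and partners had a mean difference of 0.05 and did not shift (camera adjusted p = 0.110). Its members of smallest p were Col4a1, a collagen gene, at 0.16 (SE 0.06), and L1cam.

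At the level of single probe sets 15 of 628415 changed, 10 lower and 5 higher. All 8 that carried a gene name were lower in the knockout and belonged to 6 genes of chromosome 7. The probe set of the transcription factor Mef2a changed by -2.37 on the log2 scale (SE 0.15, limma adjusted p = 0.000466). Emc10 changed at 2 probe sets, by -2.25 (SE 0.16) and -1.71 (SE 0.18), the ribosomal protein gene Rps3 by -2.23 (SE 0.21), Plekhb1 by -2.59 (SE 0.28) and the clock transcription factor Arntl by -2.68 (SE 0.32). A predicted gene, 2410002F23Rik, changed at 2 probe sets, by -1.72 (SE 0.19) and -1.80 (SE 0.21). The adjusted p-values were 0.00101 for the first Emc10 probe set, 0.0146 for Rps3 and 0.0446 to 0.04998 for the rest. The 7 probe sets without a name differed by -1.92 to 1.78, 5 of them higher. The number of calls was not firm. It was 2 to 9 when any 1 array was left out and 0 with the replicate number as a block. It was 3 after quantile normalization again, 2 without an intensity filter, 66 with the stricter filter and 102 with the trended and robust prior.

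The named probe sets that changed, and the changed genes Myo7a and Tmem159, lay on chromosome 7 on one side of Klk8. Counting tested genes from Klk8, 2410002F23Rik stood 16 genes away, Emc10 26, Mef2a 215, Myo7a 388, Rps3 406, Plekhb1 429, Arntl 623 and Tmem159 675. Small p-values that did not pass were found on the other side too: Cd33 (13 genes away) and Etfb (16 genes away) each held 1 probe set with an unadjusted p under 0.001. Among the 1920 named probe sets within 100 genes of Klk8, 18 had an unadjusted p under 0.001, against 1.92 expected, and 14 of the 18 were lower in the knockout. On the rest of the chromosome 55 of 15741 did, 46 of them lower. On all other chromosomes 145 of 225286 did, against 225 expected, and 35.9% were lower. The odds of such a probe set lying on chromosome 7 were 6.44 times those of other probe sets (Fisher's exact test, one-sided, p = 1.93e-29, probe sets not being independent). At the gene level 13 of 39 genes with a p under 0.001 were on chromosome 7 (odds ratio 5.90, Fisher's exact test, p = 4.92e-06).

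**Figure D3:**
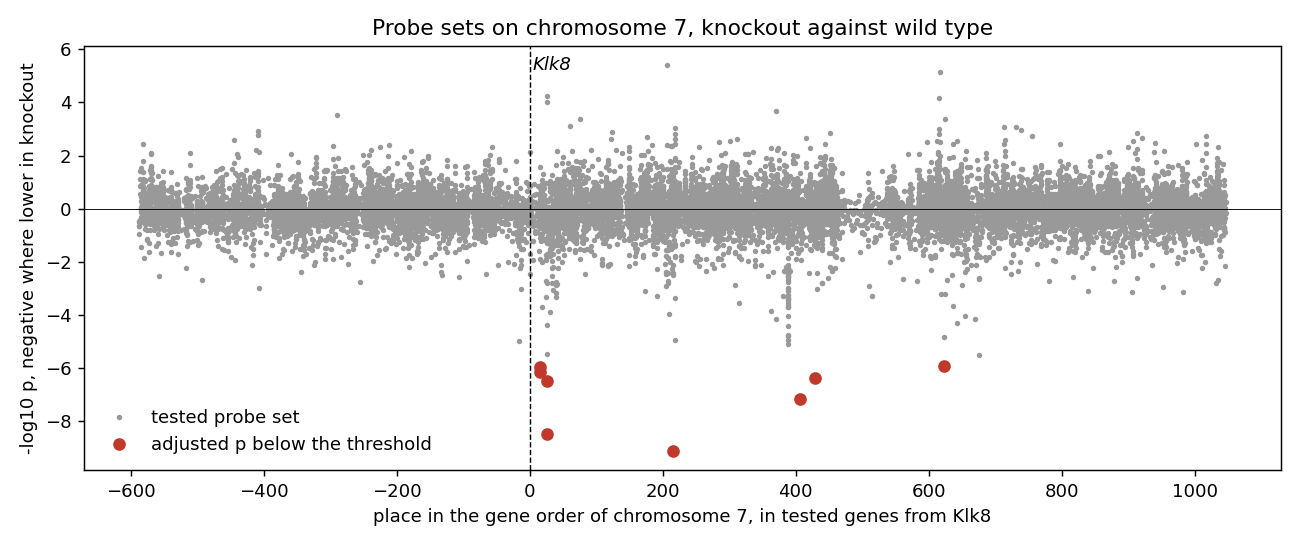
Probe sets of chromosome 7 in gene order (horizontal axis, in tested genes from Klk8 at the dashed line) against the -log10 p of knockout against wild type, drawn negative where the knockout was lower. Red dots are the 8 probe sets past the threshold; most p-values under 0.001 lie near Klk8, on either side, or further to its right, with 1 such probe set more than 50 genes to its left.

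Relative use of exons passed the test in 276 of 16367 genes (limma diffSplice, Simes p, Benjamini-Hochberg threshold 0.05). The 10 of smallest p were Mef2a, Arntl, Btbd10, Emc10, Plekhb1, Trip12, Rps3, 2410002F23Rik, Lrp8 and Pik3c2a, and all except the ubiquitin ligase Trip12 and the reelin receptor Lrp8 lie on chromosome 7. In those 8 genes the leading probe set was lower in the knockout relative to the rest of its gene, for example by -2.26 in Mef2a and -3.12 in Btbd10, while the gene level of Mef2a differed by -0.22 and that of Btbd10 by -0.03. Trip12 and Lrp8 had a leading probe set higher by 1.54 and 1.64 relative to the gene. Chromosome 7 held 40 of the 276 genes (odds ratio 2.02, Fisher's exact test, one-sided, p = 0.00012), and the leading probe set was relatively lower in 24 of the 40 and in 102 of the 276. On simulated data the test made 794 false calls where probe sets of a gene differed in spread and 16 where they shared it. The first setting took the estimated spread of each probe set as the true one. This overstates how much spreads differ, so 794 is not the number to be awaited on the real arrays. Of 60 splits of the arrays into 5 and 5, 12 gave at least 276 genes, the real split included. The count is therefore not firm. With a separate variance for each probe set, chosen after seeing the data, 6 genes passed, Emc10, Mef2a, Rps3, 2410002F23Rik, Arntl and Plekhb1, all on chromosome 7. Btbd10 did not pass that test (Simes adjusted p = 0.564), and another probe set led there, higher by 0.81 relative to the gene.

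Of the 35 gene lists, 15 shifted as sets (camera, preset correlation), 7 down and 8 up in the knockout. No list passed with an estimated correlation, where the smallest adjusted p was 0.227, and none with fry, where it was 0.106. No member of these lists passed over all genes tested with all 10 arrays and no weights or covariates, so members are given as values. The median difference over all genes was 0.00 on the log2 scale.

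Other settings ended further calls of lists. With the median over probe sets these were the neuropeptide, circadian, glutamate receptor, basolateral amygdala, striatum and cortex lists, and with the stricter intensity filter the neuropeptide, stress and circadian lists. The ribosomal call ended without the filter, with median polish and with at least 1 probe set per gene. The following settings were chosen after seeing the data. Without wild-type arrays 4 and 5 the calls of the Klk8 neighbour, neuropeptide, stress, circadian, basolateral amygdala and cortex lists ended, and with the first component as a covariate that of the basolateral amygdala list. With the hypothalamus list mean as a covariate the calls of the Klk8 neighbour, neuropeptide, ribosomal, glutamate receptor, presynaptic, circadian, excitatory neuron, myelin, central amygdala and cortex lists ended.

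Markers of the hypothalamus, which lies beside the amygdala in a coronal slice, shifted down, with 16 of 18 members lower, a median of -0.21 and a camera adjusted p of 7.08e-06 (adjusted p = 0.227 with an estimated correlation). Adjusted over the list alone, 6 members passed. They were the neuropeptide genes Pmch (-1.88, SE 0.39), Oxt (-0.63, SE 0.16) and Avp (-0.68, SE 0.22; the gene Avp at -0.43 without wild-type array 1), and the transcription factor genes Sim1 (-0.49, SE 0.16), Nkx2-2 (-0.22) and Fezf1 (-0.26), the last 2 named after their values were seen. Pmch was at 7.19 to 7.59 on wild-type arrays 1 to 3, at 5.41 and 5.35 on wild-type arrays 4 and 5, and at 4.34 to 4.93 on the knockout arrays. The gene Pmch passed over all genes in 4 of 23 other settings: without wild-type array 5 (-2.19, adjusted p = 0.0457), with array weights (0.0456), and, chosen after seeing the data, without wild-type arrays 4 and 5 (1.73e-05) and with the first component as a covariate (0.0115). The neuropeptide list, which holds Pmch, Oxt and Avp too, also shifted down (22 of 28 lower, median -0.11, camera adjusted p = 0.0116, adjusted p = 0.227 with an estimated correlation), with 2 members past the threshold adjusted over the list alone. The call of the list neuropeptides ended with the stricter intensity filter (list mean -0.08, adjusted p = 0.116) and with the median over probe sets (-0.14, 0.107). Nmb, neuromedin B, went the other way at 0.31 (SE 0.10).

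Markers of other parts of the dissected area moved down beside them. Markers of the central and medial amygdala were lower in 14 of 18 members, with a median of -0.15 (camera adjusted p = 0.000799, adjusted p = 0.227 with an estimated correlation), with Dlk1 at -0.25 (SE 0.09), Zic1 at -0.22 (SE 0.08) and Ptk2b at 0.17 (SE 0.07). Markers of striatum and intercalated cells were lower in 17 of 18, with a median of -0.17 (camera adjusted p = 9.81e-05, adjusted p = 0.481 with an estimated correlation). Among them were Rasd2 at -0.23 (SE 0.08), the enkephalin gene Penk at -0.32 (SE 0.15), the dopamine receptor gene Drd2 at -0.27 (SE 0.14) and Six3 at -0.20 (SE 0.09). Oligodendrocyte and myelin genes were lower in 15 of 15, with a median of -0.28 (camera adjusted p = 1.05e-05, adjusted p = 0.474 with an estimated correlation), and Trf was at -0.44 (SE 0.18), Opalin at -0.40 (SE 0.16), Fa2h at -0.33 (SE 0.13) and Cldn11 at -0.28 (SE 0.11). In the last 2 lists the wild-type arrays themselves spread widely, from 0.46 on array 2 to -0.40 on array 5 for myelin genes, as log2 means centred over the 10 arrays, and knockout array 4 was the lowest for striatal genes at -0.46. Without that array the mean of the list markers: striatum and intercalated cells moved from -0.18 to -0.09 (adjusted p = 0.0363), the gene Penk to -0.16 and the gene Drd2 to -0.15, and with the median over probe sets the call of the list ended (0.0649). Without wild-type array 5 the mean of the list markers: oligodendrocyte and myelin moved from -0.26 to -0.39. No member of these 3 lists passed when adjusted over the list alone.

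Lists of synaptic genes shifted up. In dissected tissue such a shift cannot be told apart from a different mix of tissue on the arrays, which was not tested for these lists. The postsynaptic scaffold and adhesion list was higher in 30 of 33 members, with a median of 0.07 (camera adjusted p = 2.56e-05, adjusted p = 0.227 with an estimated correlation). Its leading members were Kalrn at 0.25 (SE 0.08) and Tiam1 at 0.22 (SE 0.08), and the scaffold genes Dlgap1 at 0.19 (SE 0.07) and Dlgap2 at 0.18 (SE 0.07). Ionotropic glutamate receptors were higher in 11 of 17 (median 0.07, camera adjusted p = 0.00617, adjusted p = 0.227 with an estimated correlation), led by Grin2b, Gria3 at 0.25 (SE 0.09), Grin2a and Gria1 at 0.18 (SE 0.08); without wild-type array 2 this call ended (list mean 0.06, adjusted p = 0.0578). Presynaptic vesicle genes were higher in 22 of 28 (median 0.06, camera adjusted p = 0.00256, adjusted p = 0.448 with an estimated correlation), with Unc13a at 0.21 (SE 0.07), Syn3 at 0.25 (SE 0.08), the vesicular glutamate transporter Slc17a7 at 0.24 (SE 0.09) and Unc13b at 0.17 (SE 0.07). Slc17a7 lies on chromosome 7, 61 genes from Klk8, and 1 of its 18 tested probe sets had an unadjusted limma p under 0.001. Without wild-type array 5 the mean of the list presynaptic vesicle moved from 0.05 to 0.03. No member of the 3 lists passed when adjusted over the list alone. The postsynaptic list mean was lowest on wild-type arrays 4 and 5, at -0.14 and -0.06, against -0.02 to 0.01 on the other wild-type arrays and 0.03 to 0.07 on the knockout arrays.

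Markers of excitatory neurons and of cortex-like tissue moved up with the synaptic genes. Excitatory neuron markers were higher in 10 of 13 (median 0.11, camera adjusted p = 0.0105, adjusted p = 0.227 with an estimated correlation), with Arpp21 at 0.18 (SE 0.06), Nrn1 at 0.26 (SE 0.10) and Neurod2 at 0.18 (SE 0.09). Markers of cortex and piriform cortex were higher in 11 of 15 (median 0.07, camera adjusted p = 0.0116, adjusted p = 0.459 with an estimated correlation), with Mef2c at 0.20 (SE 0.09), Fezf2 at 0.30 (SE 0.13; the gene Fezf2 at 0.03 with the median over its probe sets), Nr4a2 at 0.26 (SE 0.13) and Ccn2 at 0.24 (SE 0.13). Markers of the lateral and basolateral amygdala were higher in 13 of 16 (median 0.09, camera adjusted p = 0.0403, adjusted p = 0.543 with an estimated correlation). Etv1 was at 0.24 (SE 0.11), Otof at 0.16 (SE 0.08), Rspo3 at 0.22 (SE 0.11) and Fign at -0.31 (SE 0.11). Without wild-type arrays 4 and 5, chosen after seeing the data, the mean of this last list turned to -0.01 and its call ended, and so did that of the cortex list, at 0.04. The call of the list markers: lateral and basolateral amygdala also ended without wild-type array 3 (list mean 0.09, adjusted p = 0.0553) or 4 (0.02, 0.155) and without knockout array 4 (0.07, 0.0749) or 5 (0.07, 0.0590). Without wild-type array 4 the mean of the list markers: excitatory neuron moved from 0.08 to 0.05 and that of the list markers: cortex and piriform from 0.09 to 0.06. No member of the 3 lists passed when adjusted over the list alone.

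**Figure D4:**
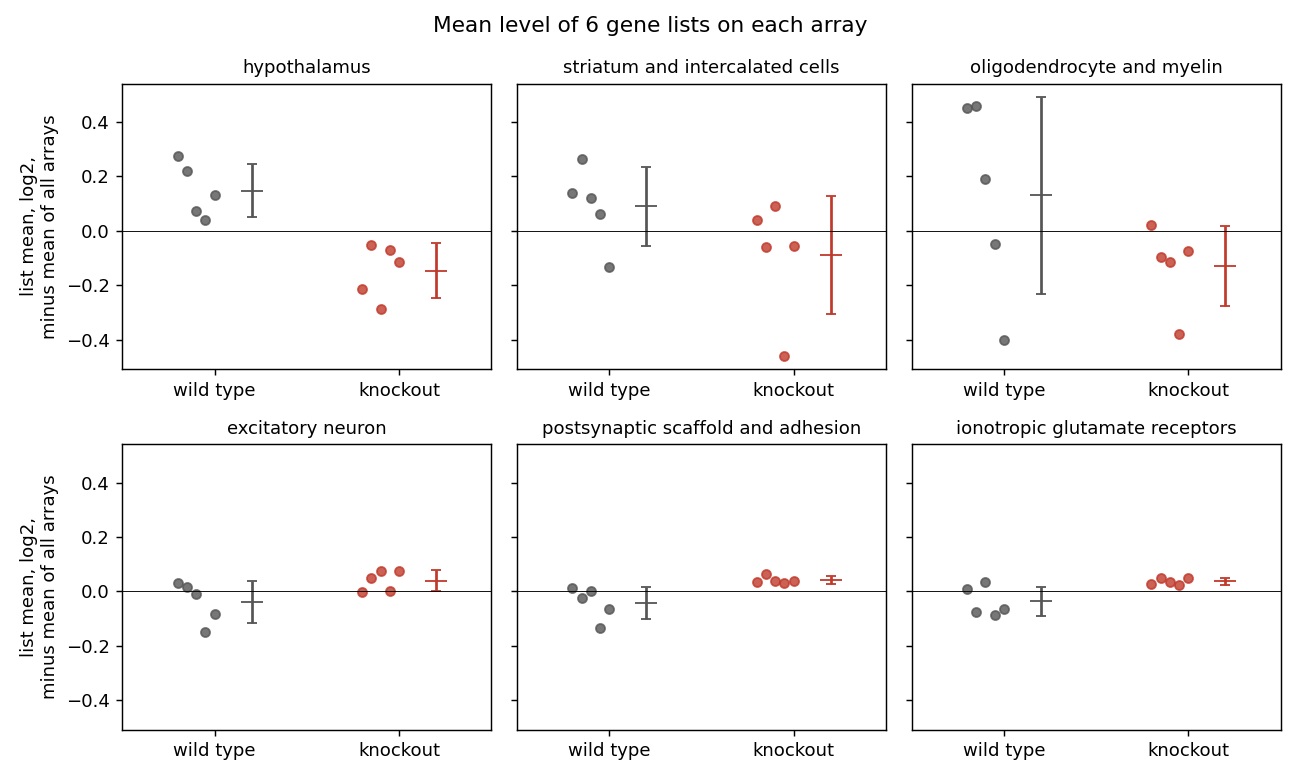
Mean log2 level of the members of 6 gene lists on each wild-type (grey) and knockout (red) array, each gene centred on its mean over the 10 arrays; dots are arrays, and the bar with whiskers is the mean ± SD of 5 arrays. The hypothalamus list separates the genotypes, with the lowest wild-type array at 0.04 and the highest knockout array at -0.05, while the myelin list spreads within wild type from 0.46 to -0.40.

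Glucocorticoid-responsive and clock genes also shifted up. In the stress list 15 of 24 members were higher (median 0.05, camera adjusted p = 0.00256, adjusted p = 0.474 with an estimated correlation), led by Zbtb16 at 0.35 (SE 0.10), Fkbp5, Per1 at 0.23 (SE 0.07) and Lcn2 at 0.53 (SE 0.19). In the circadian list 15 of 19 were higher (median 0.06, camera adjusted p = 0.00822, adjusted p = 0.543 with an estimated correlation), with the repressors Ciart at 0.33 (SE 0.11) and Per2 at 0.14 (SE 0.07) and the activator Clock at 0.15 (SE 0.09) beside Per1. No member of either list passed when adjusted over the list alone. Without wild-type array 4 or 5 the mean of the list circadian clock moved from 0.07 to 0.03 or 0.05, and without both, chosen after seeing the data, both calls ended and it turned to -0.01.

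Genes around Klk8 on chromosome 7 shifted down, with 50 of 70 members lower (median -0.07, camera adjusted p = 0.000143, adjusted p = 0.459 with an estimated correlation). Adjusted over the list alone, 6 passed: Emc10, Josd2 (-0.36, SE 0.08), Cd33 (-0.44, SE 0.10), Etfb (-0.36, SE 0.09), Klk15 (-0.51, SE 0.14; the gene Klk15 at -0.16 without the intensity filter) and Vrk3 (-0.32, SE 0.09), the last named after its value was seen. The kallikrein family, with 10 measured members, had a median of -0.09 and did not pass (camera adjusted p = 0.0579), with Klk15 and Klk8 leading. The list kallikrein family passed without wild-type array 1 (0.0117) or 3 (0.0306) and without knockout array 4 (0.00749), where the gene Klk15 also passed over all genes (-0.65, adjusted p = 0.0367). Ribosomal protein genes were lower in 22 of 26 (median -0.05, camera adjusted p = 0.0278, adjusted p = 0.657 with an estimated correlation). That list was led by Rps3, at -0.40 (SE 0.09) the only member that passed when adjusted over the list alone, whose difference was 0.00 with the median over its probe sets, and by Rps18 at -0.25 (SE 0.10), Rps16 at -0.22 (SE 0.18; the gene Rps16 at -0.00708 without knockout array 5) and Rpl3 at -0.10 (SE 0.08). The ribosomal call ended without wild-type array 2 (list mean -0.02, adjusted p = 0.359) or 3 (-0.07, 0.0766) and without knockout array 1 (-0.07, 0.0576) or 5 (-0.06, 0.102), against a mean of -0.08 with all arrays (list ribosomal proteins).

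The remaining 18 lists did not pass. Among cell types, inhibitory neuron markers had a median of -0.12 (camera adjusted p = 0.0579), with Pvalb at -0.32 (SE 0.14) and Dlx6 at -0.21 (SE 0.09). The list markers: inhibitory neuron passed in 11 of 24 other settings, among them without wild-type array 2 (adjusted p = 0.0474), 4 (0.0212) or 5 (0.0155) and without knockout array 2 (0.0362) or 3 (0.0446), so it lay near the threshold. Choroid plexus and ependyma markers had a median of -0.16 (0.102), with Folr1 at -0.33 (SE 0.18) and Aqp1 at -0.17 (SE 0.10). The list markers: choroid plexus and ependyma passed without wild-type array 1 (0.0383) or 4 (0.00653) and without knockout array 1 (0.0288) or 2 (0.00150). Without wild-type arrays 4 and 5, chosen after seeing the data, 6 of the lists that had not passed did so: the list markers: inhibitory neuron (0.0132), the list markers: astrocyte (0.0136), the list markers: microglia (0.0338), the list markers: endothelium and mural (0.0132), the list extracellular proteases and inhibitors (0.00612) and the list nuclear-encoded mitochondrial respiratory chain (0.00021). Astrocyte markers had a median of -0.04 (camera adjusted p = 0.381; Gli3 -0.16, Slc1a3 0.16), and oligodendrocyte precursors one of -0.04 (0.605; C1ql1 -0.19, Olig1 -0.20). Microglia had a median of -0.05 (0.406; Siglech 0.12, Cx3cr1 -0.14), endothelium and mural cells one of -0.05 (0.188, but 0.0490 without wild-type array 5 for the list markers: endothelium and mural; Ly6a -0.22, Vtn -0.16) and meninges and fibroblasts one of -0.06 (0.543; Igf2 -0.18, Slc6a13 -0.19). Thalamus markers had a median of -0.08 (camera adjusted p = 0.215; Ptpn3 0.21, Lef1 -0.14). Hippocampus markers had a median of 0.05 (0.277; Wfs1 -0.16), and Spink8 was the 1 member that passed when adjusted over the list alone.

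Among functional groups, Eph receptors and ephrins had a median of 0.01 (camera adjusted p = 0.381), with Epha4 at 0.23 (SE 0.09) and Epha2 at -0.19 (SE 0.07). Immediate early genes of neuronal activity had a median of 0.04 (0.277), with Ptgs2 at 0.24 (SE 0.09) and Egr1 at -0.20 (SE 0.08). Extracellular proteases and their inhibitors had a median of -0.07 (0.107), with Timp4 at -0.22 (SE 0.08) and Prss12, neurotrypsin, at 0.24 (SE 0.09). The list extracellular proteases and inhibitors passed without wild-type array 4 (0.0317) or 5 (0.0183). Perineuronal and brain matrix genes had a median of 0.06 (0.0805, but 0.0183 without an intensity filter for the list perineuronal and brain extracellular matrix), with Tnc at 0.23 (SE 0.08) and Ncan at 0.17 (SE 0.07). GABA signalling genes had a median of -0.03 and a mean of -0.01 although camera pointed up (0.946), with Gabra2 at 0.28 (SE 0.10) and Gabra5 at 0.18 (SE 0.10). Monoamine and opioid receptors had a median of 0.00 (0.635), with a mean whose sign turned when arrays were centred or normalized again, and Htr1a was at 0.23 (SE 0.08). Innate immune and interferon genes had a median of -0.09 (0.123), with Psmb8 at -0.32 (SE 0.11) and Nfkbia at 0.22 (SE 0.10). Heat shock and unfolded protein genes had a median of 0.02 (0.406; Sdf2l1 -0.18, Hspb1 -0.15), and respiratory chain genes one of -0.03 (0.184; Cox8a -0.19, Cox6a1 -0.25). The list nuclear-encoded mitochondrial respiratory chain passed without wild-type array 4 (0.0322) or 5 (0.00706). Besides Hbb-b1, the measured blood cell genes Alas2, Slc4a1 and Ptprc differed by -0.09, -0.12 and 0.15, and the Y-linked genes Eif2s3y and Kdm5d by 0.25 (SE 0.09) and 0.15 (SE 0.11), without a list test. The number of shifted lists was 13 to 19 without any 1 array and 9 with the median over probe sets.

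Among the genes given as values, leaving out 1 array moved some differences by more than 1.5 times. Without wild-type array 1 the gene Cox6a1 was at -0.16, the gene Cx3cr1 at -0.08, the gene Ly6a at -0.10 and the gene Vtn at -0.10. Without wild-type array 2 the gene Gria1 was at 0.11, the gene Pvalb at -0.22 and the gene Folr1 at -0.21. Without wild-type array 4 the gene Etv1 was at 0.16, the gene Nfkbia at 0.14, the gene Gabra5 at 0.11, the gene Kdm5d at 0.07, the gene Nr4a2 at 0.17 and the gene Slc1a3 at 0.11. Without knockout array 3 the gene Kdm5d was at 0.09 and the gene Sdf2l1 at -0.12, without knockout array 4 the gene Vtn at -0.10, and without knockout array 5 the gene Lcn2 at 0.35. Genes with a difference under 0.1 in size were not compared in this way.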

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

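Among 340 groups of 5 arrays, 1 array stood far from the other 4 in 23, where about 1 in 20 groups, or 17, would do so by chance. The value given is the gap to the nearest array as a share of the whole range. Among genes, the lowest knockout array stood apart for Grin1 (array 1, 0.763), Wfs1 (array 4, 0.766), Rps16 (array 5, 0.833), Tiam1 (array 3, 0.796), Psmb8 (array 3, 0.720) and Lef1 (array 3, 0.751). The highest knockout array stood apart for Grin2a (array 3, 0.847), Nrn1 (array 4, 0.735), Ptpn3 (array 3, 0.718) and Aqp1 (array 2, 0.753). In wild type, the lowest array stood apart for Nmb (array 3, 0.735) and Gria1 (array 2, 0.819), and the highest for Gria3 (array 3, 0.876), Dlk1 (array 1, 0.775), Dlx6 (array 2, 0.733), Igf2 (array 2, 0.717) and Slc6a13 (array 2, 0.826).

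For list means, knockout array 4 was the highest of its group for the kallikrein family (0.719) and the lowest for striatum and intercalated cells (0.731), and knockout array 2 was the highest for the postsynaptic list (0.787). Among probe sets past the threshold, knockout array 2 was the lowest for the Rps3 probe set (0.722), knockout array 5 the highest for the unnamed probe set 5519971 (0.737) and knockout array 3 the highest for the unnamed probe set 4426922 (0.746). Igf2 and Slc6a13, both of the meninges list, stood apart on the same wild-type array, where Dlx6 and Gria1 also did.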

How the results depend on the processing

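The 5 arrays per genotype and probe sets near background limit all tests, and the additions named as such were chosen after seeing the data. Leaving out each array in turn gave 2 to 6 changed genes (0 to 2 higher, 2 to 4 lower), 2 to 9 probe sets, 173 to 331 exon usage genes, 13 to 19 lists and a Klk8 difference of -0.25 to -0.04. The gene count was 2 without knockout array 2, 3 or 5, and exon usage 173 without knockout array 1. Myo7a and Hbb-b1 kept their side of the threshold in all planned settings that tested them, while Pisd-ps3 lost it in 4 and Tmem159 in 8 of them; with at least 1 probe set per gene, where more genes were tested, 2 genes passed and 0 were higher.

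Probe set counts were 3 after quantile normalization again, 2 without an intensity filter, 66 with the stricter filter and 102 with the trended and robust prior. Exon usage gave 623 without the filter, 94 with the stricter one and 37 with the F test. Lists fell to 9 with the median over probe sets and to 0 with an estimated correlation and 0 with fry. Klk8 differed by -0.39 over the probe sets above the filter, where it passed at an exact permutation p of 0.0476. The cause was not tested.

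The replicate number as a block gave 3 genes, 0 probe sets, 448 exon usage genes and 16 lists. Same-numbered arrays correlated, in their deviations from the group means, at 0.282, 0.0817, 0.265, 0.412 and 0.240, and 7 of the 10 arrays correlated best with their own number. The second pair lay under 0.1, so the numbers were not taken to pair the samples. All these correlations were positive, however, so pairing is not excluded, and the main tests leave it out. The other splits of the arrays with 368 and 124 genes each kept both arrays of numbers 1, 3, 4 and 5 on one side, so arrays of one number share some structure. With the block all 15 probe set calls ended, and so did that of the gene Tmem159 (adjusted p = 0.0847).

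Without wild-type arrays 4 and 5 there were 5 changed genes, 0 higher and 5 lower, 3 probe sets and 453 exon usage genes. With the first component as a covariate 5 genes were lower. With the hypothalamus list mean as a covariate 0 genes passed, 0 higher and 0 lower. The differences were then -0.65 for the gene Myo7a, -1.73 for the gene Hbb-b1, -0.55 for the gene Tmem159 and 0.60 for the gene Pisd-ps3, all smaller in size than without it. The covariate follows genotype (r = -0.856), so a loss of precision cannot be told apart from a real adjustment. A separate variance per probe set gave 6 exon usage genes. These were chosen after seeing the data.

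Reversed signs were mostly small, the largest values being 0.107 for the gene Hspb1 and 0.0733 for the list ribosomal proteins. They were in results that had not passed, unless named otherwise. They were the gene Six3 at 0.00775 without the intensity filter, the gene Ephb2 at -0.0202 and the list markers: hippocampus at -0.0149 with the stricter one, and the gene Nrg1 at -0.0092 and the gene Erbb4 at -0.00099 with array weights. With the median over probe sets they were the gene Grin1 at -0.0362, the gene Rps3 at 0.00176, the gene Pvalb at 0.0197 and the gene Hspb1 at 0.107. The list monoamine and opioid receptors was at -0.00032 after quantile normalization again, -0.00017 with centred arrays, -0.0213 with the stricter filter and -0.00943 with median polish. Leaving out each array in turn gave -0.000705 to 0.0631 for the gene Nrg1, -0.0142 to 0.0779 for the gene Erbb4, -0.00898 to 0.0335 for the list Eph receptors and ephrins, -0.0104 to 0.04998 for the list activity-induced immediate early genes and -0.0567 to 0.0297 for the list GABA signalling. It also gave -0.0105 to 0.031 for the list monoamine and opioid receptors, -0.0263 to 0.0587 for the list heat shock and unfolded protein, -0.0418 to 0.0493 for the list markers: oligodendrocyte precursor and -0.0687 to 0.0351 for the list markers: meninges and fibroblast. Without wild-type arrays 4 and 5 the reversed values were the gene Nrg1 at -0.024, the gene Erbb4 at -0.0573, the gene Kdm5d at -0.0200, the list Eph receptors and ephrins at -0.029, the list activity-induced immediate early genes at -0.0195 and the list neuropsin substrates and partners at -0.0232. The others there were the list perineuronal and brain extracellular matrix at -0.0165, the list monoamine and opioid receptors at -0.0282 and the list heat shock and unfolded protein at -0.0700, with the called list circadian clock at -0.0106 and list markers: lateral and basolateral amygdala at -0.0105. With the hypothalamus covariate the called lists were the list Klk8 neighbours on chromosome 7 at 0.034, the list neuropeptides at 0.00474 and the list ribosomal proteins at 0.0733.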

Other observations

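Tests chosen only after their result was seen were those of chromosome 7 as a whole, of the alpha-globin probe sets and of the probe sets shared by Pisd copies, and the 4 added alternatives.

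Along chromosome 7 the probe sets with an unadjusted limma p under 0.001 were spread unevenly. In stretches of 100 tested genes, the genes more than 50 places to one side held 1 such probe set in all, and the stretch around Klk8, which reaches to both sides of it, held 16 of 809. On the other side the stretches held 2, 8, 1, 24, 1, 9 and 5, and then 1 in each of the last 3. The 73 probe sets, 3 of them of Hbb-b1, which has no place in the gene order, came from 45 genes, 37 of which had only 1. Myo7a had 17 of its 46 tested probe sets among them and Emc10 6 of its 13, while Synm and Tbc1d17, chosen after their values were seen, had 2 each.

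The real grouping was compared with other splits of the 10 arrays into 5 and 5. For genes, 3 of 100 splits, the real one included, gave at least the real count of 4, which is under the share of 0.05 set beforehand. The other 2 of the 3 gave 368 and 124 genes, far above the real count. The split with 368 set wild-type arrays 1, 2 and 3 with knockout arrays 1 and 3 against the rest, which points to a structure of the arrays unrelated to genotype. Both splits parted arrays of numbers 1 and 3 from those of 4 and 5, and each number holds 1 array of each genotype. With the replicate number as a block 3 of the 4 genes still passed. With the first component as a covariate, chosen after seeing the data, all 4 did. This argues against that structure as the source of the 3 genes. The share by itself still does not exclude chance for this count. For probe sets, 1 of 100 splits, the real one, gave 15, and the highest other gave 0. For lists, 2 of 100 gave as many as the real 15, the highest other also giving 15. Most other splits passed some lists too, for example 10 with wild-type arrays 1, 3 and 4 and knockout arrays 2 and 3 on one side. A list past the threshold at the preset correlation is therefore not by itself a sign of genotype. For exon usage, 12 of 60 splits gave as many as the real 276, the highest other 1047, so chance cannot be excluded for that count.

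The differences on chromosome 7 may come from DNA around Klk8 that stayed from the strain in which the deletion was made, with sequence differences under probes. The line had been backcrossed for 12 generations, and the length of any kept DNA was not tested. The changed genes reached 675 genes from Klk8, at Tmem159. On that side the stretch 50 to 149 genes away held 2 probe sets with an unadjusted limma p under 0.001, 0 of them lower. The stretch 350 to 449 genes away held 24, 23 of them lower. A single kept piece reaching as far as Tmem159 was therefore not shown. Probe sets past the threshold had odds 125.2 times higher of lying within 100 genes of Klk8 (Fisher's exact test, one-sided, p = 2.65e-07; 4 of the 8 named ones, 2 each of Emc10 and 2410002F23Rik, which are not independent, with the 7 unnamed ones left out), and those with a p under 0.001 odds 6.44 times higher of lying on the chromosome, with a lower level in the knockout more often than elsewhere (odds ratio 8.17). Whether whole genes changed cannot be told for the chromosome 7 genes as a set. For each of 72 probe sets with a p under 0.001, the gene's other probe sets were set against it. Their median difference was a median of 0.152 of its own, with an interquartile range of 0.0219 to 0.578. Genes entered once per such probe set, Myo7a 17 times and Emc10 6 times. Single genes differed: 17 of 46 tested probe sets of Myo7a had such a p, while 37 of 45 genes held only 1. Less blood in the knockout tissue is argued against for Hbb-b1, because the alpha-globin probe sets differed by a median of -0.34, against its own -1.81, and would have had to fall much further. An effect of neuropsin loss on these genes stays open, because the deletion and its flanking DNA are in the same animals.

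The lower Pmch, Oxt and Avp may reflect more hypothalamic tissue in the wild-type dissections. The other 15 measured members of that list differed by a median of -0.18, 13 of them lower (camera p = 0.000217, or 0.0728 with an estimated correlation). Of its 18 measured members, 9 are also in another list, and 8 lay above 6.50 on the array, so the tissue may express part of them itself. With the list mean as a covariate no gene passed, but that mean lies between 0.04 and 0.27 in wild type and between -0.29 and -0.05 in the knockout, so the covariate can hardly be parted from genotype. A direct effect of neuropsin on these genes was not tested and stays open, as does the spread within wild type, where Pmch on arrays 4 and 5 was near the knockout level. Markers of other regions and cell types moved as well. For the synaptic lists a different tissue mix and an effect of neuropsin loss cannot be told apart.

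The rise of Pisd-ps3 may be signal shared between near-identical Pisd copies. The 15 probe sets annotated to several genes including a Pisd copy were all higher, by a median of 0.65. Pisd-ps2 differed by 0.43. The change of a single copy, or a different number of copies in the donor strain, stays open and was not tested.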
